A study of Ovis aries with 10 samples.

How the data were processed

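Gene expression was measured in the left ventricular free wall of 10 singleton fetal sheep, 5 from ewes infused with cortisol and 5 from ewes infused with vehicle. Per the labels, Cy3-labelled cRNA was made from total RNA and read on a 1-colour Agilent sheep array, and the spots were measured with Agilent Feature Extraction 10.1.1.1. Per the file headers, the deposited intensity of each spot had its background subtracted and was detrended across the array, with a substitute value where a spot was not above background. It was not normalised between arrays. The deposited mean and median intensity of each spot and the local background carry no such correction. The authors' deposited value table was on a log2 scale, found from its values: within each array its order equalled that of the median spot intensity minus the local background (Spearman correlation 1.0), its quantiles were nearly equal between arrays, and genes were not centred. The array medians of that table lay between 5.77 and 5.79. The steps that made it are not given in the sources used here, so its background correction stays inferred.

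Groups were taken from the labels. The free-text description of 9 of the 10 samples names another muscle, the biceps femoris, while their titles, source and tissue fields all name the left ventricle. The latter were followed, and marker genes of both tissues were examined. The arrays lay on 2 slides, each holding both groups, with 3 control and 3 cortisol arrays on slide 1 and 2 of each on slide 2.

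Each array held 15744 spots, of which 536 were controls and left out. Spots marked by Feature Extraction as non-uniform, as population outliers or as not found were left out. Not-found spots numbered 500 to 1184 per array, of which 110 to 208 were well above background, so this mostly removed dim values. The log2 of the processed intensity minus the array's 75th percentile over non-control spots was used as the level, and spots of one probe were averaged, giving 15008 probes. A probe was tested where it was well above background on at least 5 of the 10 arrays, whatever their group, which left 10261 probes with 1504 missing values. No spot was saturated. Between 63.5% and 73.2% of spots per array were well above background, and the number of arrays limits the precision.

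Of all probes, 1656 (11.03%) carried a gene name, for 1010 names, and the other 13352 were counted without a name. Names were updated through the reference table of sheep genes by RefSeq accession for 713 probes, by symbol for 502, by gene identifier for 142 and by synonym for 26. A further 87 older names were updated by hand after the data were examined, and 186 probes kept the name in the files. Among the probes tested, 962 had a name, for 627 genes. For a gene with several probes, the probe with the highest mean level over all arrays stood for it. No genome was used here, so no coordinates are given.

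Treatment was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, over the 22 of 40 lists with at least 5 tested genes, and adjusted over those lists. For the list tests only, a missing value took the mean of its group for that probe. The code was tested on simulated data with the spreads of these probes and 200 changed probes: limma called 11 of 50 probes changed 1.5-fold, 33 of 50 changed 2-fold, 45 of 50 changed 3-fold and 47 of 50 changed 4-fold, with 10 false calls.

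Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold, each direction filled to 10 with the genes of smallest unadjusted p, and said not to pass. It added 14 genes of cortisol action and cardiac identity where measured, and for each list described the 2 to 4 members of smallest unadjusted p. Gene lists, tests and most alternatives were also fixed before the data were examined. The alternatives were another background correction (normexp with an offset of 50), quantile and median scaling, the authors' deposited table, other filters on dim probes, flagged spots kept, the slide or the replicate number as a block, each slide alone, array weights, another variance model, other thresholds, other list tests and leaving out each array. Leaving out an area of lost signal on 1 array was added after seeing the data. That area was found as spots whose neighbourhood (8 rows and 4 columns each side, at least 10 bright spots) had a median more than 0.75 log2 below the same spots on the other arrays.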

Results

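The series asked what about 25 days of raised maternal cortisol did to gene expression in the late-gestation fetal heart. Ewes received 1 mg/kg/day of cortisol, the main glucocorticoid of sheep, or vehicle from about day 115 of pregnancy. Tissue was taken soon after labour began, at 139 to 144 days. The treatment groups held 7 ewes each, and left ventricular RNA of 5 fetuses per group was analysed, 1 array per fetus. The 75th percentile of spot intensity ranged from 177 to 286 scanner units over the arrays. Levels below are log2 relative to that percentile of the same array, and differences are cortisol minus control with the standard error of limma.

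No probe changed in the fetal left ventricle at the threshold set. Of 10261 probes, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.990. At an unadjusted p under 0.05 limma gave 333 probes, 164 higher and 169 lower with cortisol, where chance alone would give about 513. This count and its balance depend on the processing: normexp gave 852, 781 higher and 71 lower, quantile normalisation 105 higher and 222 lower, and the authors' deposited values gave 178 higher and 83 lower, each with 0 called. With slide as a block the count stayed at 0 (377 unadjusted), and it was 0 within slide 1 (463 unadjusted) and 0 within slide 2 (288 unadjusted). On cortisol replicate 4 an area of spots between rows 64 and 136 had lost signal, 1303 spots or 8.57% of those that were not controls. Without that area the count was again 0 (361 unadjusted), and without the whole array it was 0 (469 unadjusted).

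**Figure D1:**
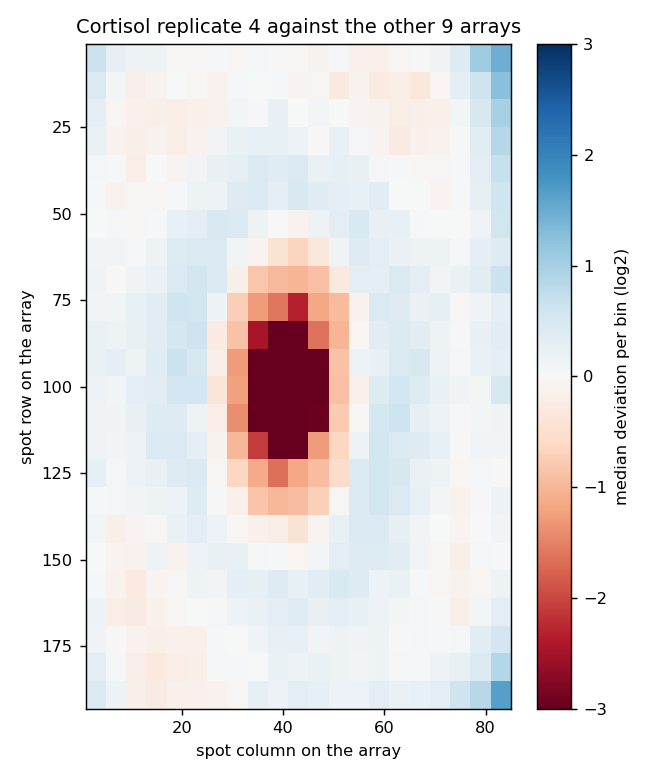
Deviation of cortisol replicate 4 from the median of the other 9 arrays, as the median log2 deviation of bright spots in bins of 8 rows by 4 columns, with the colour scale ending at -3 and 3. An area within rows 64 to 136 and columns 28 to 52 is low, and the 1303 spots left out there had a median deviation of -0.99. The lowest bin had -4.68. Bins towards the ends of the right edge are high, such as 1.47 in the bin starting at row 1 and column 81, and were not left out.

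The cortisol-sensing genes did not differ beyond the spread between fetuses. NR3C2, the mineralocorticoid receptor (listed under an older locus name), had a level of 2.22 ± 0.19 (SD, n = 5) in controls and 2.24 ± 0.28 (SD, n = 5) with cortisol. NR3C1, the glucocorticoid receptor, was measured by 1 probe, with a log2 difference of -0.58 ± 0.62 (SE). That probe lay in the area of lost signal, and without it the difference turned to 0.12. HSD11B1, which regenerates active cortisol, had -0.16 ± 0.50 (SE), and its probe also lay in that area and turned to 0.37 without it. A second HSD11B1 probe outside the area had -0.15. HSD11B2, which inactivates cortisol, had -0.37 ± 0.40 (SE) and was well above background on 4 control and 3 cortisol arrays. With the normexp background correction the HSD11B1 and HSD11B2 differences took the other sign, 0.06 and 0.15. PER1, a clock gene that glucocorticoids induce, was well above background on 2 of 10 arrays and was not tested. MYH7, the slow and ventricular myosin heavy chain, had 5.07 ± 0.18 (SD, n = 5) in controls and 5.04 ± 0.37 (SD, n = 5) with cortisol. FKBP5, TSC22D3, KLF9, ZBTB16, PDK4, NPPA, NPPB and MYH6 had no probe under those names and were not analysed here.

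The rule named 10 genes as higher with cortisol, and 0 of them passed the adjusted threshold. INHBA, the activin beta A subunit, had a difference of 0.91 ± 0.30 (SE), a 1.88-fold higher mean. TXNIP, a glucose-regulated thioredoxin inhibitor, had 0.67 ± 0.27 (SE) and was above the control mean on 4 of 5 cortisol arrays. MYC had 0.54 ± 0.21 (SE), BCL2, an inhibitor of apoptosis, 0.47 ± 0.17 (SE), and RPS12 0.47 ± 0.15 (SE). COL6A1, a collagen VI chain, had 0.45 ± 0.15 (SE), while its other probe had -0.02. SMAD1, which carries bone morphogenetic protein signals, had 0.44 ± 0.13 (SE) and ANGPT2, an endothelial growth factor, 0.41 ± 0.17 (SE). CREB had 0.28 ± 0.11 (SE) and EIF3A 0.24 ± 0.10 (SE). In limma all 10 had an adjusted p of 0.990, and apart from TXNIP each was above the control mean on 5 of 5 cortisol arrays. The choice by small p on these same arrays favours such agreement, so it adds no support.

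The 10 genes named as lower did not pass either, each with an adjusted p of 0.990 in limma. RPL32, a ribosomal protein gene, had the smallest unadjusted p of all probes in limma (0.000309). Its difference was -0.56 ± 0.11 (SE), and it was below the control mean on 5 of 5 cortisol arrays, which its choice by small p favours. Its 1 tested probe was dim, with a control level of -3.02 ± 0.15 (SD, n = 5), against 8.46 ± 0.24 (SD, n = 5) for RPS12. TIE1, an endothelial receptor, had -0.53 ± 0.13 (SE) and PPY -1.19 ± 0.24 (SE), each measured on 3 of the 5 cortisol arrays after flagged spots were left out, and -0.39 and -0.97 with these kept. MYOD1, a skeletal muscle transcription factor, had -0.59 ± 0.17 (SE). PPY was well above background on 4 control and 1 cortisol arrays and MYOD1 on 4 and 2. With normexp both turned, to 0.05 and 0.06. FGF18 had -0.61 ± 0.27 (SE), POMC -0.56 ± 0.22 (SE), TM7SF2 -0.46 ± 0.15 (SE), PYGB, a glycogen phosphorylase, -0.35 ± 0.13 (SE) and RAB9A -0.19 ± 0.08 (SE). The POMC and PYGB probes lay in the area of lost signal and had -0.54 and -0.33 without it. CLC4 had -0.66 ± 0.24 (SE) with a value on only 1 cortisol array, -0.04 with flagged spots kept, and turned to 0.08 with normexp.

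**Figure D2:**
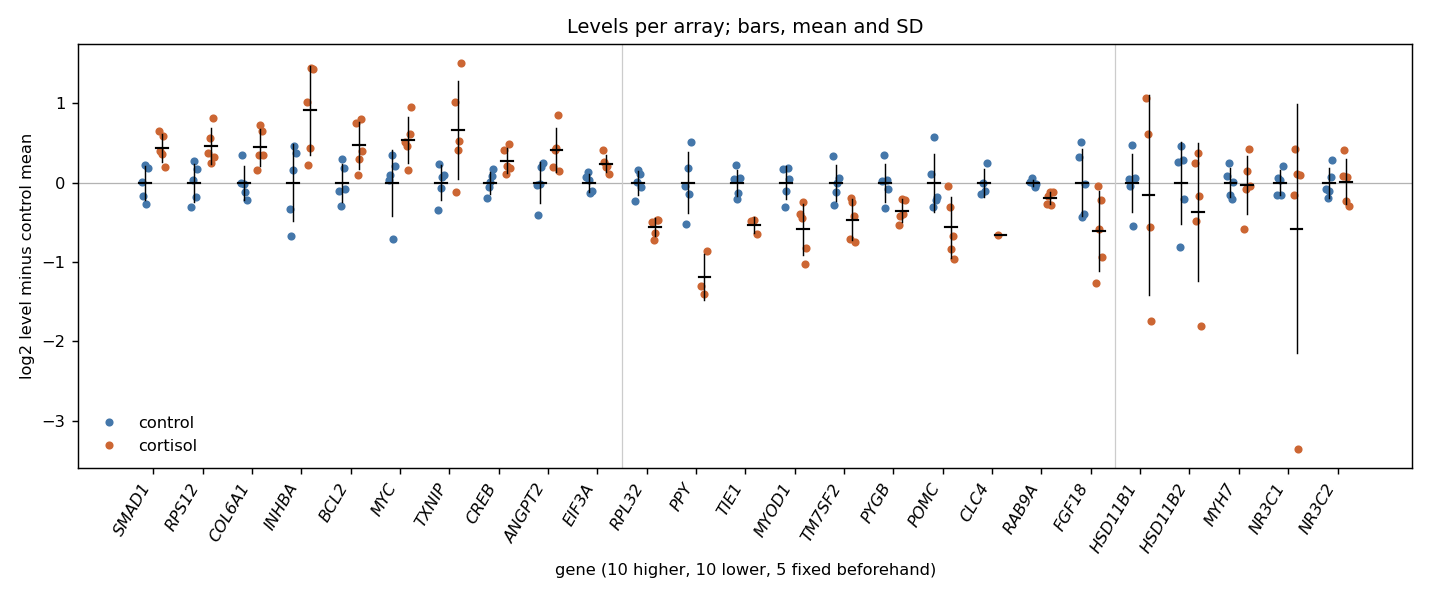
Log2 level of each array minus the control mean for the 10 genes of smallest unadjusted p in each direction and the 5 measured genes fixed beforehand, with control arrays in blue, cortisol arrays in orange, and lines for the mean and SD. RPL32 shows a difference of -0.56, and the low NR3C1 point is cortisol replicate 4 at a log2 level of -3.36.

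No gene list passed the adjusted threshold. Of 22 lists tested with camera, 0 passed 0.05, and 14 leaned higher with cortisol. The closest were the fatty acid uptake and oxidation genes, with 7 of 9 measured members higher and a median difference of 0.31 (adjusted p = 0.135, and 0.934 with an estimated correlation). Members were CPT1A, which admits long-chain fatty acids to mitochondria, at 0.86 ± 0.37 (SE), its muscle form CPT1B at 0.31 ± 0.13 (SE), FABP5 at 0.70 ± 0.50 (SE) and SLC25A20, the carnitine carrier, at 0.32 ± 0.24 (SE). The median was 0.33 within slide 1 and 0.32 within slide 2, and with slide as a block the adjusted p was 0.150. Leaving out 1 array gave a call in 3 cases, with an adjusted p of 0.00806 without control replicate 3, 0.0247 without cortisol replicate 2 and 0.0186 without cortisol replicate 4. It was also called within slide 2 (0.0443, against 0.342 within slide 1) and with array weights (0.0168). Over 25 other choices of values, filters, blocks and arrays the list leaned higher each time, with an adjusted p from 0.00806 to 0.503, under 0.05 in 5 of the 25, and fry gave 0.869. No member passed when adjusted over the list alone. FABP4, LPL and PPARG of this list are also fat cell markers.

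Growth signalling genes had 11 of 16 members higher, with a median of 0.16 and an adjusted p of 0.389. MYC, FGF2 at 0.41 ± 0.17 (SE) and EDN1, the vasoconstrictor endothelin 1, at 0.64 ± 0.27 (SE) were the members of smallest p. Cell cycle genes had 8 of 10 members lower, with a median of -0.19 and an adjusted p of 0.331, among them HMMR at -0.29 ± 0.16 (SE), CCND3 at -0.23 ± 0.14 (SE) and CCNA2 at -0.39 ± 0.35 (SE). The cell cycle list was called without cortisol replicate 2 (adjusted p = 0.0247), while without cortisol replicate 3 its adjusted p was 0.910. Both values are at the preset correlation, and over all arrays an estimated correlation gave 0.934. The 10 measured glucocorticoid-responsive genes split 4 higher and 6 lower (adjusted p = 0.846). Their median of -0.07 and the camera direction, higher, differed in sign. Beside TXNIP, they held MTHFD2 at 0.36 ± 0.35 (SE), PCK1 at -0.51 ± 0.51 (SE) and HIF3A at -0.26 ± 0.26 (SE).

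The energy and protein synthesis lists with enough tested genes did not pass. Complex I of oxidative phosphorylation and the mitochondrial ribosome had 1 tested gene each, and the TCA cycle list had 0. No list test was run on them, so most mitochondrial energy genes were not examined. Of 57 names listed for oxidative phosphorylation complexes II to V, 5 were tested. They had a median of -0.03 (adjusted p = 0.798), with ATP5MC1 at -0.12 ± 0.11 (SE) and COX5A at 0.15 ± 0.15 (SE). The 10 glycolysis and glucose uptake genes had a median of -0.05 (adjusted p = 0.764). At the preset correlation they leaned lower within slide 1 (median -0.13, adjusted p 0.204) and were called higher within slide 2 (median 0.25, 0.0443). An estimated correlation gave 0.938 over all arrays and 0.438 for the difference in treatment effect between slides. Over all arrays the insulin-regulated transporter SLC2A4 had -0.22 ± 0.18 (SE) and LDHA 0.19 ± 0.27 (SE). The 18 cytosolic ribosome genes had a median of -0.02 (adjusted p = 0.594, and 0.934 with an estimated correlation). With normexp the list was called lower by camera at the preset correlation (0.000356), and an estimated correlation was not tried there. In the main setting 1 of them, RPL32 with its dim probe, passed when adjusted over the list alone (0.00556). RPL13A at -1.16 ± 0.84 (SE) lay in the area of lost signal and had -0.20 without it. Apoptosis regulators had 6 of 9 members lower, a median of -0.13 and an adjusted p of 0.747, with BCL2 the only one under an unadjusted 0.05.

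Markers of other cell types were examined beside these groups. Endothelial markers had 8 of 11 members higher, a median of 0.22 and an adjusted p of 0.565. At the preset correlation they were called higher within slide 2 (0.0443, against 0.859 within slide 1). An estimated correlation gave 0.934 over all arrays and 0.371 for the difference in treatment effect between slides. TIE1 passed when adjusted over the list alone (0.0371), with values on only 3 cortisol arrays after flagged spots were left out. Its difference was smaller with these kept. TEK, the other receptor of that family, had 0.58 ± 0.24 (SE). Extracellular matrix and fibroblast genes had 12 of 16 higher and a median of 0.13 (adjusted p = 0.551), with MMP2 at 0.35 ± 0.16 (SE) and COL3A1 at -0.34 ± 0.18 (SE). That list was called without control replicate 4 (0.0232) and had 0.966 without control replicate 1, both at the preset correlation. Over all arrays an estimated correlation gave 0.934. Genes of the fat cell list had 8 of 10 higher and a median of 0.25 (adjusted p = 0.565), with PLIN5 at 0.38 ± 0.28 (SE) and PLIN1 at -0.21 ± 0.14 (SE). Whether each marks fat cells alone in heart tissue was not tested. The smooth muscle genes CNN1 and MYLK had 1.01 ± 0.51 (SE) and 0.32 ± 0.18 (SE), and 2 genes are too few for a list test. HBB, a haemoglobin chain of red cells, had 0.83 ± 0.87 (SE), and the lymphocyte gene CD3E -0.36 ± 0.47 (SE).

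**Figure D3:**
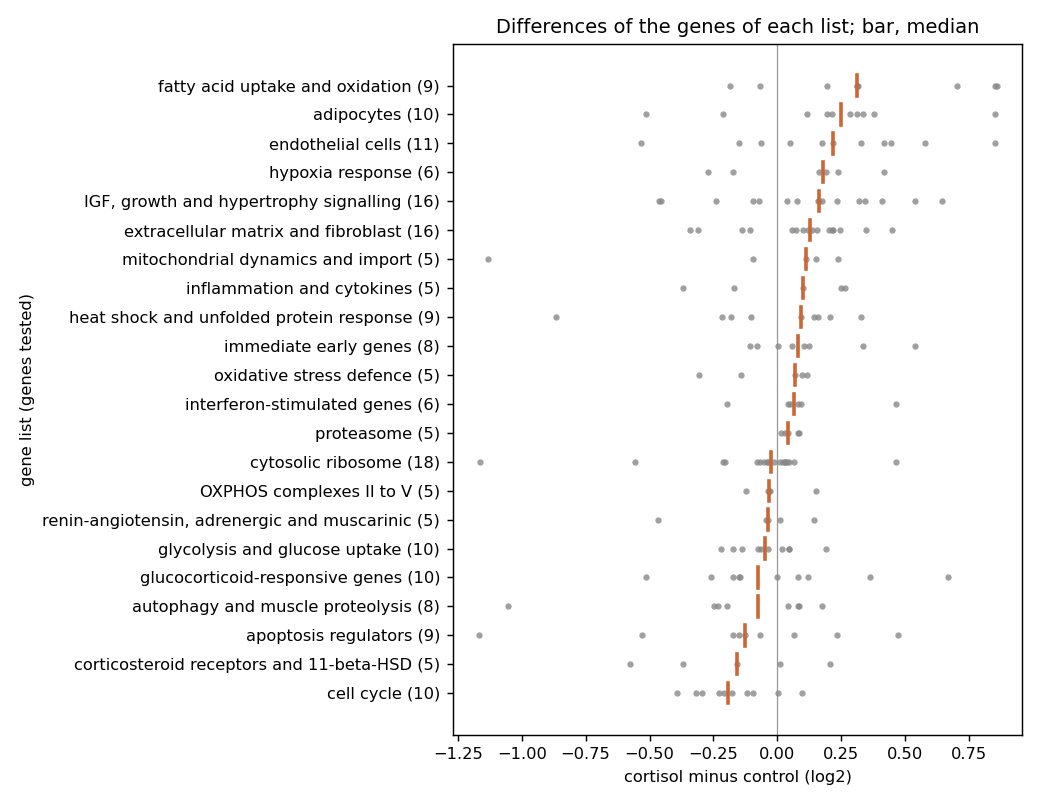
Log2 difference of each tested gene in the 22 lists, cortisol minus control, as points, with the median of each list as an orange bar and the number of genes in brackets. The fatty acid list has the highest median, 0.31, and the cell cycle list the lowest, -0.19.

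Marker probes of heart and skeletal muscle were set out for each array because of the conflicting descriptions. The probes of MYH1 and MYH2, fast skeletal myosins listed under older names, and of MYF5 were well above background on 0 of 10 arrays. The probes from the cardiac sarcomere list, MYH7, TPM1 and CRYAB, had mean array percentiles of 97.7 ± 0.31, 99.8 ± 0.08 and 99.7 ± 0.07 (SD, n = 10). MYH7 is also made in slow skeletal fibres. No skeletal muscle array was at hand for comparison, so the high levels of these probes do not separate the tissues. The skeletal probes TNNC2 and PYGM had 62.1 ± 2.82 and 92.7 ± 1.73 (SD, n = 10). MYOD1 passed when adjusted over the 3 tested skeletal genes alone (0.0158), but it was well above background on 4 control and 2 cortisol arrays and turned to 0.06 with normexp. The labels of control replicate 1 name only the left ventricle. There the tested skeletal probes TNNC2, MYOD1 and PYGM were above the mean of the other arrays by 0.59, 0.52 and 0.49 in log2. The others had an SD of 0.15, 0.39 and 0.43 (n = 9). Of the skeletal probes well above background on 0 of 10 arrays, MYH1 differed there by 1.37, MYH2 by -0.74 and MYF5 by -0.47. The cardiac probes MYH7, TPM1 and CRYAB were also higher there, by 0.11, 0.22 and 0.25 (SD 0.29, 0.33 and 0.19), and no test was run on these. No probe passed for the difference between the 2 slides in limma with treatment as a covariate (0 adjusted, 934 unadjusted). Chance alone would give about 513 unadjusted of the 10261 probes, so the absence of a call does not show that the slides are alike.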

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

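The tests on the area of lost signal, the fat cell markers, the simulated 1.5-fold changes and the splits balanced over slides were chosen after those results were seen. The slide block was planned as an alternative, and its use to weigh an explanation was chosen after its result was seen. Of 102 groups of values examined for a single array far from the other arrays of its group, 6 had one, and chance flags about 1 in 20.

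Of these, 5 were cortisol replicate 4. Its median spike-in variation was 28.6%, against 6.74% to 10.8% in the other cortisol arrays, and its probe variation was 31.2%, against 8.74% to 10.5%. NR3C1 had a level of -3.36 there, against -0.16 to 0.42. The mean of the corticosteroid receptor list was -1.49, against -0.56 to -0.23, and that of the apoptosis list -1.17, against -0.57 to -0.37. Spike-in control spots inside the low area were lower than those outside by a log2 difference of -1.46, with an SD of 0.25 outside, and these spots carry no fetal RNA. With the area left out, the array's mean correlation with the others rose from 0.940 to 0.9775, above the lowest of the other 9 (0.9751). A different RNA over the whole array is thus argued against, and a local loss of signal is the candidate explanation.

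The last was the hypoxia response list in control replicate 4, with a mean of -0.80 against -0.53 to -0.46.

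The count of 0 probes was weighed next. Leaving out the low area gave 0 called probes, which argues against that area as the reason. Slide as a block also gave 0, which argues against a constant difference between the slides as the reason. Such a block cannot show treatment effects that run in opposite directions on the 2 slides, so these are not argued against. With 200 probes changed 1.5-, 2-, 3- or 4-fold in one simulation at the spreads of these fetuses, 66% of 2-fold changes were called. Many changes of that size beside as many larger ones were thus unlikely to be missed. The larger changes ease the adjusted threshold, and 2-fold changes alone, or fewer of them, were not simulated, so these stay open. Of 1.5-fold changes 22% were called, and small changes stay open too. Of 100 splits of the 10 arrays (126 are possible), the real one included, 83 gave at least as many probes at an unadjusted p under 0.05 as the real 333. The highest of the others had 857, so chance cannot be excluded for the 333. Of the 47 of these with the slides balanced as in the real one, 40 did, with 633 as the highest of the others. These counts ask about an excess and cannot explain an absence of called probes. Among the 99 other splits 5 called any probe, at most 2.

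The fatty acid list was the third. Of the same 100 splits, 84 gave some list with an unadjusted p as small as the real 0.00614, the smallest of the others being 1.36e-07, so chance cannot be excluded. Of the 47 balanced over slides, 38 did. Adipocyte markers outside that list had a median of 0.22 (0.216), between 0 and the list's 0.31, so that fat cells in the tissue pieces cannot be told apart from a change within heart muscle cells. These genes of the adipocyte list went both ways, with PLIN5 at 0.38 and PLIN1 at -0.21. Whether each of them marks fat cells alone in heart tissue was not tested. For the count of lists, the real 0 means that 100 of 100 splits gave as many whatever their values, which says nothing on chance, with 7 as the highest of the others. Among the 99 other splits 73 called at least 1 list, and 33 of the 46 others balanced over slides did. A call of some list at the preset correlation was thus common among splits that do not follow treatment. The alternatives were not run on these splits.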

How the results depend on the processing

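The alternatives that leave out the area of lost signal were chosen after seeing the data. The count of 0 called probes stayed at 0 under every fit run, leave-one-out fits included (0 to 0), and at an adjusted p under 0.10; the unadjusted threshold gave 333. Unadjusted counts ranged from 238 without control replicate 1 to 469 without cortisol replicate 4 over the fits that leave out 1 array. No filter on dim probes gave 492 of 14984 probes, and normexp gave 852, of which 91.7% were higher against 49.2% in the main setting. The higher share was 32.1% with quantile normalisation, 61.0% with median scaling and 68.2% in the authors' deposited table. The median difference over all probes lay between -0.0331 and 0.0641. The count of 0 lists became 1 with normexp (cytosolic ribosome, lower), 1 with array weights (fatty acid), 2 within slide 1 (interferon-stimulated genes higher, heat shock lower) and 7 within slide 2 (interferon-stimulated genes lower; hypoxia, heat shock, immediate early, fatty acid, glycolysis and endothelial higher), and leaving out 1 array gave 0 to 2. These were 1 without control replicate 3 (fatty acid), 1 without control replicate 4 (extracellular matrix), 2 without cortisol replicate 2 (fatty acid, cell cycle) and 1 without cortisol replicate 4 (fatty acid); the cause was not tested. In the main setting the count was 0 with an estimated correlation, fry or the mean of all probes. These tests were not run in the settings that gave a call. With no filter on dim probes 1 probe differed between the slides. Mean skeletal and cardiac marker percentiles, 26.7 and 99.7, moved by less than their SD. The replicate block gave 0 called probes (397 unadjusted) and 0 lists. Same-numbered arrays correlated at 0.22, -0.01, 0.15, 0.19 and 0.02, where the highest correlation with another number was 0.024, 0.105, -0.008, -0.004 and 0.055. Thus 3 of the 5 control arrays correlated best with their own number, and a pairing by number stays open. The main fit did not take the numbers as pairs, and the splits did not keep them together. Of 3200 values of 129 genes under the alternatives, 164 had another sign than in the main setting and 0 were called (adjusted p 0.585 to 1.00). The changes of sign were spread over 68 of the 129 genes, and only 61 kept their sign under every alternative. With normexp PCK1, HIF3A, SLC2A1, CCNA2 and PLIN1 took the other sign, at 0.11, 0.02, 0.09, 0.09 and 0.05. The cause was not tested for these; PPY, which turned too, was well above background on 4 control and 1 cortisol arrays.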

Other observations

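The tests of a slide difference in the treatment effect were chosen after the data were seen. In a fit with treatment by slide, 5 of the 22 lists differed between slides with camera at the preset correlation, and 0 of 22 did with an estimated correlation. The interferon-stimulated genes, which respond to antiviral signals, had a median difference of 0.46 within slide 1 and -0.43 within slide 2, with ISG15 at 0.65 and -0.85, MX1 at 0.47 and -1.20 and IRF1 at 0.82 and -0.06. The heat shock and unfolded protein genes went the other way, with medians of -0.30 and 0.31, including the chaperone HSPA5 at -0.44 and 1.02. The hypoxia response list had -0.19 and 0.67, with SLC2A1, the basal glucose transporter, at -0.70 and 0.62 and VEGFA, the vascular growth factor, at -0.29 and 0.85. Control replicate 4, on slide 2, held the low mean of that list, -0.80.

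At the preset correlation the adjusted p was 0.00388 for the interferon and for the hypoxia list and 0.00840 for the heat shock list. The glycolysis and the immediate early gene lists were the others, at 0.0161 and 0.0145, while oxidative stress defence had 0.131. With an estimated correlation camera gave an adjusted p of 0.3675 for the interferon and heat shock lists. It gave 0.333 for the hypoxia and immediate early gene lists and 0.438 for glycolysis, so these calls rest on the preset correlation. In the fit with treatment by slide limma called 0 probes (523 unadjusted, near the count of about 513 that chance alone would give for 10261 probes). Slide 2 held 2 arrays per group, so single fetuses weigh heavily there.

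Other lists did not pass for treatment over all arrays. Adjusted p from camera was 0.715 for the proteasome, 0.751 for inflammation and cytokines, for mitochondrial dynamics and import and for the renin-angiotensin and adrenergic list, 0.959 for oxidative stress defence and 0.747 for autophagy and muscle proteolysis. SLC25A5, an ADP/ATP carrier, and CTSB, a lysosomal protease, had log2 differences of -1.13 and -1.05, and both probes lay in the area of lost signal, with 0.17 and -0.00 without it.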
